A study of Mus musculus with 6 samples.

How the data were processed

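Total RNA from mouse retina at E15.5 was sequenced on Illumina instruments in 6 libraries, 3 per genotype, each made from a pool of 8 retinas, per the labels. The animals were C57BL/6 mice. The control group carried the T2fx allele and is called wild type by the submitters. The other group carried T2Isl1, an allele that places Isl1 at the Tbr2 (Eomes) locus. Retinas were kept in RNAlater and RNA was taken with an RNeasy mini kit, per the labels' protocols. Groups were assigned from the sample labels.

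The submitters' processing notes name CASAVA, TopHat2 2.1.1, Cufflinks 2.1.1 and the mouse build mm10, with no order of steps. The gene annotation behind the values is not given in the sources used here. The deposited table has the layout of a Cuffdiff gene comparison, with 1 value per gene and group into which the replicate libraries had been combined. Those group values were read as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), a unit inferred from the tool the authors name, since the file header says only value. The authors' log2 fold change is the log2 of knock-in over control without a pseudocount, per the file headers. It matched the log2 ratio of the group values to within 1.08e-05. The authors' test score is signed as the fold change and was not used further. Each gene also has the authors' p-value and an adjusted q-value, per the file headers. The smallest p-value among the rows analysed was 5e-05, with a q-value of 0.0116. If q came from the Benjamini-Hochberg method, those values mean that at least 2320 genes were adjusted together.

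The rows analysed were those of chromosome 1, and other chromosomes were not analysed here. They comprised 1140 complete rows, and 1 incomplete row was left out. A first run of 666 rows named 619 plus-strand genes and 1 minus-strand gene by the annotation, and a second run of 474 rows named 447 minus-strand and 6 plus-strand genes. The last complete row ended at position 156719102. They named 910 of the 1208 protein-coding genes annotated on chromosome 1 in GENCODE M21, which uses the mm10 assembly. By strand these were 534 of 615 plus-strand genes and 376 of 593 minus-strand genes. The authors had tested 646 rows. The other 494 were not tested, and their highest value was 0.516 FPKM. Of the 1140 rows, 216 were at 0 in both groups, 14 had no gene name, 14 joined several names and 16 repeated a name. Positions in the table count from 0, so 1 was added to each start. With that step 412 starts equalled an annotated transcript start, against 36 without it.

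No new test of single genes was made, because values per library were not used here. Genes were called changed when the authors' q-value was under 0.05. No SD, interval or replicate check could be given for any gene, and library depth is unknown. The labels describe each library as a pool of retinas and do not say whether pools shared litters.

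Before the data were examined, 26 gene lists, the counts of called genes, the Fisher's exact tests of the lists and the rule for named genes were fixed. The matched random lists and the rank correlations described below were not part of that plan. The rule took Isl1 and Eomes, then the 12 called genes with the highest and the 12 with the lowest fold change among those with at least 1 FPKM in the higher group and values above 0 in both. From each list it took the 4 called members with the smallest q-value. It named the 10 called genes, since Isl1 and Eomes were not analysed here. Other genes in the text were named after their values were seen, as members of the fixed lists or as stated beside them. A further result is not reported here.

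The share of called genes in each list was compared with all other tested rows by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 18 lists that had a tested member. Direction among called genes was compared by two-sided Fisher's exact test for lists with at least 5 called members. Both treat genes as independent, which neighbouring gene copies are not. For lists with at least 5 tested members, the median log2 fold change was placed among 10000 random lists drawn from the 30 tested genes nearest in level, as a description of these group values. Further draws were matched also on locus length, transcript length or GC content. Rank correlations across genes used 100000 two-sided permutations, with Benjamini-Hochberg adjustment over the 19 correlations computed. Transcript length was that of the longest annotated transcript, found for 611 of the 646 tested rows (94.6%).

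Alternatives covered stricter q-value thresholds, floors of 1 and 5 FPKM, minimum folds of 1.5 and 2, a pseudocount of 1, and rows with joined or repeated names left out. The methods were tested on simulated data built on the 646 tested rows with 200 runs each. The share test found a list given 5 of 10 calls in 100% of runs and passed in 0% with calls placed at random. Matched lists found 5 genes lowered by 1 on the log2 scale in 100% of runs, and unchanged lists fell below the 5th percentile in 6.5%. The matched-list runs shuffled fold changes across genes and matched on level and locus length only. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.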

Results

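Gene expression was compared between control retinas (T2fx) and retinas in which Isl1 was expressed from the Tbr2 locus (T2Isl1) at E15.5 (embryonic stage), with 3 libraries per group. Isl1 is a LIM-homeodomain transcription factor of developing retinal ganglion cells, and Tbr2, encoded by Eomes, is a T-box factor of a subset of these cells. The comparison asks which retinal genes differed between the genotypes. It was read from 646 rows of chromosome 1 that the authors had tested. The group value is a single FPKM estimate, so no replicate error could be given. Isl1 and Eomes were not analysed here, and the expected change at the knock-in allele was therefore not checked.

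Most tested chromosome 1 genes had similar levels in both genotypes. In the authors' deposited table, the median level of tested rows was 10.7 FPKM in control and 10.4 FPKM in knock-in retinas, and the median log2 fold change was 0.01. Of these rows, 96.7% differed by less than 1.5-fold. At a q-value under 0.05, 1 gene was higher and 9 genes were lower in the knock-in. All 10 had the same q-value of 0.0116 in the authors' deposited table, the smallest among the rows analysed. At an unadjusted p-value under 0.05 there were 7 higher and 17 lower rows, 24 in all, against 32.3 expected by chance among 646. Thus the calls on this chromosome rested on a small set of genes with large differences, and most of them were crystallins. Rows at the smallest p-value were 1.55% of those tested here, and 0.625% without the gamma crystallins. If q came from the Benjamini-Hochberg method, at most 0.431% of all the authors' tested genes can be there. Chromosome 1 holds the gamma crystallin cluster, so the crystallin majority need not hold for other chromosomes.

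**Figure D1:**
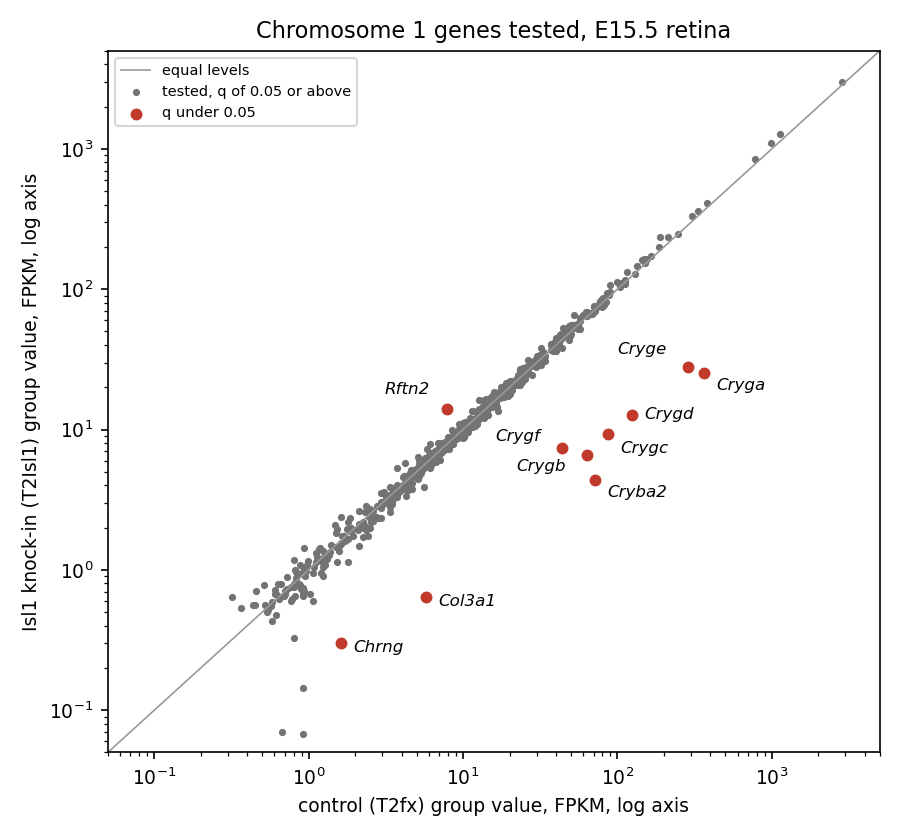
Group values of the 646 tested chromosome 1 rows, in FPKM on log axes, with control on the horizontal and Isl1 knock-in on the vertical axis. Each point is a gene, the line marks equal levels, and the 10 red points are genes with a q-value under 0.05, of which only Rftn2 lies above the line.

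Crystallin genes, which encode the structural proteins of the lens, had lower values in the knock-in group. More lens tissue in 1 or more control pools and an effect of the genotype cannot be told apart here. All 7 tested members of the lens list were called, each lower, by 5.91-fold to 16.4-fold. Summed over these 7 genes, the level was 1038 FPKM in control and 93.6 FPKM in knock-in retinas in the authors' deposited table, an 11.1-fold difference. These genes made up 5.0% of all chromosome 1 FPKM analysed in control and 0.45% in knock-in retinas. The remaining list member with a row, Lgsn, was not tested and was listed at 0 in both groups.

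The 6 gamma crystallins were each lower in the knock-in. Cryga (chromosome 1, 65100389 to 65103363, minus strand, mm10) went from 364 to 25.3 FPKM in the authors' deposited table, a log2 fold change of -3.85. Cryga thereby moved from rank 6 to rank 166 among the tested rows. Cryge (65048557 to 65051163, minus strand) went from 285 to 27.9 FPKM, a log2 fold change of -3.35 in the authors' deposited table. Crygd (65061838 to 65063440, minus strand) had 123 and 12.7 FPKM in the authors' deposited table, a log2 fold change of -3.28. Crygc (65071525 to 65073532, minus strand) had 86.7 and 9.25 FPKM, with -3.23 on the log2 scale in the authors' deposited table. For Crygb (65080222 to 65082290, minus strand) the authors' deposited table gave 63.4 and 6.60 FPKM and a log2 fold change of -3.26. These 5 genes form a cluster from 65048557 to 65103363. Crygf (65926522 to 65928304, plus strand) lies outside the cluster and had the smallest change of the lens genes, from 43.9 to 7.44 FPKM (log2 fold change -2.56, the authors' deposited table). The beta crystallin Cryba2 (74889934 to 74893143, minus strand) had the largest relative change of the 10 called genes, from 71.3 to 4.35 FPKM and -4.03 on the log2 scale in the authors' deposited table.

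Called genes were more frequent in the lens list than among other tested rows (7 of 7, two-sided Fisher's exact test, p = 1.33e-14, adjusted over 18 lists 2.40e-13). With the gamma crystallins counted as 1 gene, a setting chosen after seeing the data, the adjusted p of Fisher's exact test was 0.000878. All 7 were also called when adjusted over the list alone, a looser adjustment that these already called genes could not fail. On direction alone, 0 lens genes were higher and 7 lower, against 1 higher and 2 lower among the other called genes (two-sided Fisher's exact test, p = 0.3, the smallest value below 1 that these counts allow). An exact permutation test of the mean log2 fold change, which also reads the size of change, gave p = 0.0167 over 120 arrangements. Its comparison genes were only Rftn2 at 0.84, Chrng at -2.43 and Col3a1 at -3.18, the last within the range of the lens genes. The test was not run without Rftn2, the only called gene that was higher. The gamma crystallins are close sequence copies, so the division of reads between them is uncertain, and Cryga overlaps the same-strand gene Gm28845.

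Outside the lens list, 2 genes fell and 1 rose. Col3a1 (45311538 to 45349706, plus strand), the chain of type III collagen of connective tissue, fell from 5.76 to 0.637 FPKM in the authors' deposited table, a log2 fold change of -3.18. Chrng (87205811 to 87211835, plus strand), the gamma subunit of the fetal muscle acetylcholine receptor, fell from 1.62 to 0.30 FPKM (log2 fold change -2.43, the authors' deposited table). Rftn2 (55168824 to 55226880, minus strand), a member of the raftlin family, rose from 7.84 to 14.1 FPKM in the authors' deposited table, 1.79-fold or 0.84 on the log2 scale. With a pseudocount of 1 the log2 fold changes were -2.05 for Col3a1 and -1.01 for Chrng, from the values of the authors' deposited table. All 3 are protein-coding genes. The crystallins fell in the same comparison as Col3a1 and Chrng, by 11.1-fold in sum. For Col3a1 and Chrng too, surrounding tissue in the control pools was not excluded. Rftn2 overlaps the antisense gene Gm10561 and Col3a1 a microRNA gene, and strand-specific counting is not given in the sources used here.

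Genes near Rftn2 did not pass the test. Within 500 kb, 8 other rows were tested, and their log2 fold changes in the authors' deposited table ranged from -0.10 to 0.31, with 6 above control. Of all 646 tested rows, 54.6% were above control and only 10 were called. A lack of calls among 8 rows therefore says little. The nearby gene Mob4 had 44.7 and 52.9 FPKM (p = 0.0356 unadjusted in the authors' deposited table). These neighbours were looked up after the Rftn2 call was seen.

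Vascular and mesenchymal genes included Col3a1 as the 1 called member of 6 tested. Col5a2, another fibrillar collagen gene, had 5.56 FPKM in control and 3.88 FPKM in knock-in retinas and a q-value of 0.0588 in the authors' deposited table. Twist2, a mesenchymal transcription factor, had 0.677 and 0.0703 FPKM with a q-value of 0.623 in the authors' deposited table. By contrast, the pericyte gene Rgs5 had 7.55 and 7.18 FPKM, Cd34 had 6.66 and 6.86 FPKM and Fn1 had 11.9 and 10.6 FPKM in the authors' deposited table. The list's median log2 fold change was -0.34 and its mean -1.19, and none of 10000 level-matched random lists had so low a median (percentile 0). Its share of called genes did not pass (two-sided Fisher's exact test, adjusted p = 0.807), although 3 members passed when adjusted over the list alone. With Benjamini-Hochberg adjustment over the analysed rows alone, which also calls Col5a2, the adjusted p of Fisher's exact test was 0.0343.

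**Figure D2:**
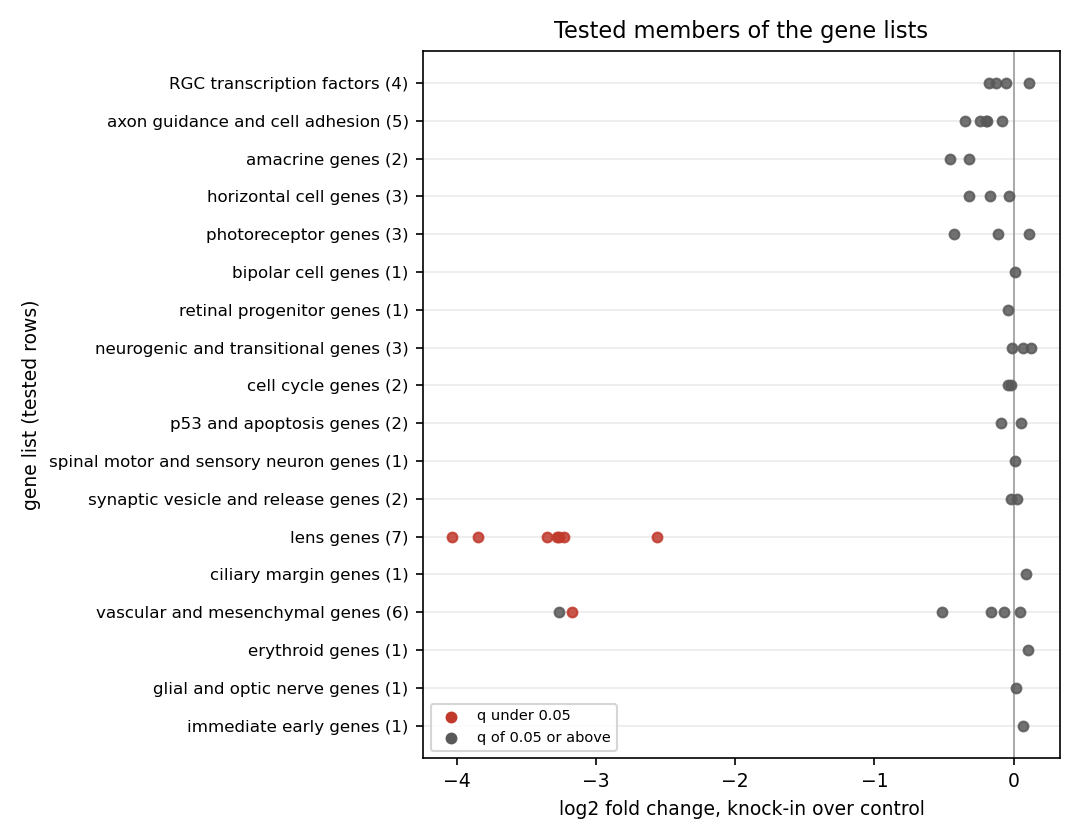
Log2 fold change (knock-in over control) of each tested member of the 18 fixed gene lists that had one, with the number of tested rows in brackets. Each point is a gene, red where the q-value was under 0.05, and the 7 lens genes lie between -4.03 and -2.56.

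Neuronal and progenitor genes of the retina had no called member among the rows analysed. Across the remaining 16 lists with a tested member there were 28 tested genes, of which 0 were called at a q-value under 0.05. Only 10 of all 646 tested rows were called, so 0 calls among 28 genes is little evidence of no change. Their log2 fold changes in the authors' deposited table ran from -0.46 for Lhx9 to 0.12 for Hes6, and the smallest q-value was 0.544. Among the 4 tested ganglion cell transcription factors, Klf7 had 31.3 and 30.2 FPKM in control and knock-in in the authors' deposited table. St18 had 2.71 and 2.40 FPKM, and Rxrg, also on the photoreceptor list, had 11.1 and 12 FPKM in the authors' deposited table. These values show no called change for the few ganglion cell factors measured, and the better-known markers of these cells were not analysed here.

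Amacrine and horizontal cell genes likewise held no call. Tfap2b, a transcription factor of both cell types, had 16.9 and 13.6 FPKM, with an unadjusted p of 0.008 and a q-value of 0.807 in the authors' deposited table. It was the 1 member that passed on each of these lists when adjusted over the list alone, of 2 tested amacrine and 3 tested horizontal cell genes. For the horizontal cell genes Slc4a3 and Tnr the authors' deposited table gave log2 fold changes of -0.04 and -0.17. Of 3 tested photoreceptor genes, Crb1 had 14.0 and 12.9 FPKM and Cnga3 had 1.53 and 1.14 FPKM in the authors' deposited table. Lhx4, the 1 tested gene of both the bipolar and the spinal motor and sensory neuron lists, had 3.38 and 3.41 FPKM in the authors' deposited table.

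The few progenitor and cell cycle genes tested, 1 of 38 and 2 of 42 list members, were close to control and do not stand for their lists. The Wnt receptor gene Fzd5, the 1 tested progenitor gene, had 68.0 and 66.2 FPKM in the authors' deposited table. The replication licensing genes Mcm3 and Mcm6 had 71.7 and 69.9 FPKM and 81.5 and 80.5 FPKM in the authors' deposited table. Of the 3 neurogenic genes, Hes6 had 380 and 414 FPKM, Btg2, also the 1 tested immediate early gene, had 79.5 and 83.4 FPKM, and Rgs16 had 26.3 and 26.1 FPKM in the authors' deposited table. The apoptosis genes Bcl2 and Phlda3 had log2 fold changes of -0.09 and 0.05 in the authors' deposited table. The 2 tested rows of the synaptic gene Rims1 had -0.02 and 0.02 on that scale in the authors' deposited table. Col9a1 of the ciliary margin had 81.1 and 86.1 FPKM, Glul of glia had 245 and 248 FPKM, and Tmcc2 of the erythroid list had 41.1 and 44.3 FPKM in the authors' deposited table. For each of the 16 lists the Fisher's exact test of called genes gave an adjusted p of 1. With 0 calls in such short lists and 10 called of 646 tested rows, that outcome was fixed and says nothing about these genes. The other 8 lists had no tested member among the rows analysed, which cover chromosome 1 in part: ganglion cell neuronal and axonal markers, Tbr2 and melanopsin cell genes, cholinergic genes, receptors and ion channels, pigment epithelium, microglia, hypoxia and sex-linked genes.

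Axon guidance and adhesion genes lay below their control values without being called. All 5 tested members had negative log2 fold changes and 0 had a q-value under 0.05. Their transcripts are long. With tested genes split by transcript length into 5 groups, they fell in groups 4 and 5, the longest. In those groups 53.7% and 78.5% of all genes were below control, so 5 of 5 below is less unusual than it looks. The semaphorin receptor gene Plxna2 had 4.26 and 3.34 FPKM, with an unadjusted p of 0.00465 and a q-value of 0.544 in the authors' deposited table. Epha4 had 3.34 and 2.82 FPKM, Cntn2 had 43.6 and 38.0 FPKM and Nfasc had 14.5 and 12.7 FPKM in the authors' deposited table. Nrp2 had the smallest difference, with -0.08 on the log2 scale in the authors' deposited table. The list's median of -0.20 stood at percentile 0.32 of level-matched random lists, 1 of 3 lists given such a percentile. The lens and vascular lists stood at percentile 0. Plxna2 passed when adjusted over the list alone.

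Genes with long transcripts had slightly lower values in the knock-in group. Across 611 tested genes ordered by transcript length into 5 groups, the median log2 fold change was 0.09 in the shortest group and then 0.04, 0.04, -0.01 and -0.08 in the longest. In the shortest group 28.5% of genes were below control, and in the longest 78.5%. The rank correlation across genes was -0.36 (Spearman's rho, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 1.58e-05 over 19 correlations). Pearson's r had the opposite sign, 0.12 (permutation p = 0.00318, adjusted 0.00403), and became -0.11 (permutation p = 0.0082, adjusted 0.00974) without the 10 called genes, 7 of which are crystallins. Genes are not independent replicates, and the trend describes these group values only. The axon guidance genes were measured in this same setting, at percentile 0.83 of random lists matched on level and transcript length and at 3.54 when GC content was matched as well.

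**Figure D3:**
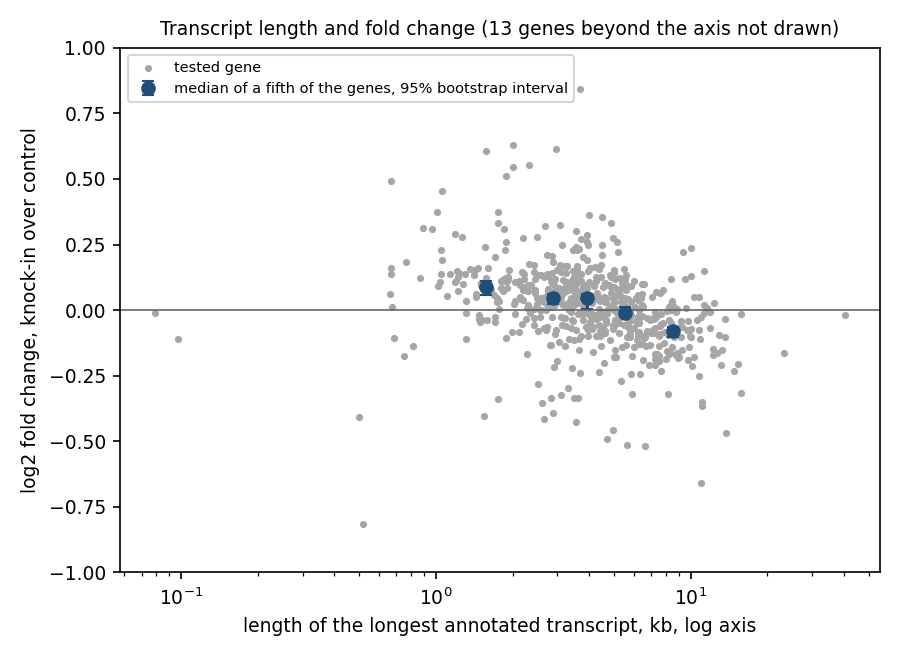
Log2 fold change (knock-in over control) of tested genes against the length of the longest annotated transcript, in kb on a log axis. Grey points are genes, and dark points with bars are medians of 5 groups by length with 95% bootstrap intervals over genes (2000 draws). The medians go from 0.09 to -0.08, and 13 genes beyond the vertical axis are not drawn.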

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

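The adjustment over the analysed rows alone, the unadjusted p-value, the count without lens genes, the gamma crystallins counted as 1 gene and the settings of the length trend were chosen after seeing the data. The other alternatives were fixed earlier. At q-value thresholds of 0.01 and 0.001, 0 genes were higher and 0 lower, because all 10 calls share the q-value of 0.0116, the smallest among the rows analysed. With a 2-fold minimum 0 genes were higher, since Rftn2 rose by 1.79-fold, and 9 remained lower. At an unadjusted p-value under 0.05, 7 genes were higher and 17 lower. Without the lens genes 2 were lower. The direction test of the lens list went from p = 0.3 to 0.0167 (exact permutation of the mean log2 fold change), which reads size as well as sign. Its few comparison genes included Rftn2, the only called gene that was higher. The adjusted p of the vascular and mesenchymal list (Fisher's exact test) was 0.0343 with adjustment over the analysed rows alone, where Col5a2 is also called, and 0.415 to 0.807 in its other settings. The lens list passed in each of its settings, with an adjusted p of at most 0.000878 (Fisher's exact test, gamma crystallins counted as 1 gene). At a floor of 5 FPKM 8 genes were lower, since Chrng has 1.62 FPKM in control, and 10 were lower with adjustment over the analysed rows alone. Taking counts within 1.5 times the main count as alike and tests by their side of the threshold, 22 settings stayed alike, 6 were weaker and 4 stronger. Several of the 22 could not differ, so the tally does not measure robustness. The lowest level of a called gene, in its higher group, was 1.62 FPKM and the smallest called fold was 1.79. A floor of 1 FPKM and a 1.5-fold minimum therefore left the same 10 calls and the same direction test. A further 13 settings of single genes and of the length trend kept their direction. A pseudocount cannot change the sign of a fold change, so for the 10 called genes that outcome was fixed. The length trend settings counted here were rank correlations, while Pearson's r changed sign when the called genes were left out. With a pseudocount of 1, Col3a1 went from -3.18 to -2.05 and Chrng from -2.43 to -1.01 on the log2 scale.

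No paired analysis was possible because the table holds 1 combined value per group and its columns carry no replicate number. For the same reason the fits without each replicate, the replicate block and other splits of the libraries were not run. The pseudocount alternatives for Isl1 and Eomes were not run, as those genes were not analysed here, and the direction test had no calls at a q-value of 0.01. Depth is unknown, so the precision of low values such as Chrng could not be stated.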

Other observations

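Several tests here were chosen only after the result was seen: the 4-fold count, the summed gamma crystallins, the median of all tested genes, the muscle and connective tissue lists (drawn up after the calls) and transcript length in place of locus length. The reasons for setting aside the bound on muscle genes were also found after its values were seen.

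Wide differences between the genotypes went in 1 direction. Among 686 rows with at least 0.3 FPKM in the higher group, 16 differed by at least 4-fold, and all 16 were lower in the knock-in. This count includes the 9 called lower genes. Of the 16, 9 were not crystallins, and besides Col3a1 and Chrng none of them was called. Chil1, a chitinase-like secreted protein gene, had 0.915 and 0.0679 FPKM, and Tnni1, the slow skeletal muscle troponin I gene, had 0.917 and 0.143 FPKM in the authors' deposited table. The authors had not tested 4 of the 16, Wnt6 (0.390 and 0.0241 FPKM), the collagen gene Col6a3 (0.444 and 0.0664 FPKM), Gm19705 (0.496 FPKM in control) and Spata45 (0.336 FPKM in control), per the authors' deposited table. Gm19705 and Spata45 were listed at 0 in the knock-in. At a floor of 0.1 FPKM 25 rows were lower and 2 higher, and at 1 FPKM 9 were lower and 0 higher.

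Smaller differences also appeared among genes that were not called. Kif26b, a kinesin family gene, had 2.41 and 1.74 FPKM with a q-value of 0.178 in the authors' deposited table. Optc, which encodes the extracellular matrix protein opticin, had 3.73 and 5.32 FPKM, with an unadjusted p of 0.0164 in the authors' deposited table. These genes were chosen after their values were seen.

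The crystallins, Col3a1 and Chrng fell together, and reads moving between gamma crystallin copies would leave their sum alike, yet the sum was 10.8-fold higher in control. A uniform scaling error left in the group values would lower all genes alike, but the median log2 fold change was 0.0134. FPKM are already scaled to the library, so a small median was likely beforehand. It speaks only against such a uniform shift. More lens, muscle and connective tissue in 1 or more control pools may explain the pattern; the bound set against it beforehand, a median above -0.25 for 5 muscle genes not yet seen, was met at -0.0754 (-0.11 for 8 connective tissue genes, Rgs5 and Fn1 among them). In hindsight that bound was a poor one. Speg, Stk11ip and Csrp1 had 10.2 to 41.1 FPKM in both groups and so would hide a little muscle. Tnni1 and Myl1, under 1 FPKM, had -2.68 and -1.28 on the log2 scale in the authors' deposited table. An outcome written beforehand for surrounding tissue was a fall of members that the retina does not express, with ubiquitous ones unchanged. It gave no level below which a gene counts as not expressed, so it could not be scored strictly. Of the 4 unseen muscle and connective tissue genes under 1 FPKM in control, 3 were below control. Surrounding tissue and an effect of the knock-in on these genes therefore cannot be told apart without values per library, and both stay open.

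The lower values of long genes were first seen for locus length (Spearman's rho -0.23 across 646 genes). GC content and level did not account for it, since the rank correlation with locus length was -0.29 adjusted for GC content and -0.19 adjusted for level. Adjusted for transcript length it was -0.0721 (permutation p = 0.0742), consistent with transcript length, or something that goes with it, carrying the trend. Transcript length kept a rank correlation of -0.33 when adjusted for the other properties, as GC content did at -0.26 and level at 0.18, so transcript length was not the sole trend. Differences in RNA integrity or library preparation and a biological effect of the genotype were not tested and stay open.

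The axon guidance genes are long, so the length trend might account for their lower values. Their median stood at percentile 1.14 of random lists matched on level and locus length and at 0.83 with transcript length instead. With level, transcript length and GC content matched together it stood at 3.54, closer to the bound of 5 set beforehand. By that bound the trend was not the whole cause, but with 5 genes, 0 of them called, the margin is small and the trend is not excluded. Unchanged simulated lists fell below the bound in 6.5% of runs. Those runs shuffled fold changes across genes, which removes the trend, and matched on level and locus length only. Their rate therefore cannot be carried over to the percentile of 3.54. A lower level of these genes in the knock-in retina is a hypothesis found and examined on the same values.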
